A study of Mus musculus with 2 samples.

How the data were processed

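Small RNA of under 30 nt, per the labels, was sequenced from the gastrocnemius of female B6CASTF1/J mice aged 2 months, in 2 libraries labelled biological replicates. The deposited values are raw counts of reads per microRNA gene, given for reads of either strand, for reads on the gene's own strand and for reads on the opposite strand. The reads were assigned to the microRNA genes of GENCODE mouse release 21 on the mm10 assembly, per the notes deposited with each library. The aligner and the counting tool are not given in the sources used here. The deposited files also list reads that were unmapped, aligned to several places, outside genes or ambiguous. These rows name no gene and were left out of library sizes and tests. Reads that aligned to several places are in no gene, so counts of genes with near-identical copies leave out any of their reads that could not be placed.

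Own-strand counts were the main values, because small RNA libraries keep the strand and because 64 microRNA genes overlap another on the other strand, where reads cannot be assigned without it. All 2202 gene identifiers in the files matched the annotation, which gave names, positions in mm10 and the gene and feature around each. Genes on the same strand within 10000 bp of each other were taken as a cluster. A gene was marked as sharing sequence when a stretch of 20 nt occurs in another microRNA gene that does not overlap it, which held for 1087 genes and for 69 of the 278 detected ones. Both definitions were chosen after the counts had been seen.

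CPM values were taken over all own-strand microRNA gene counts of a library. With 1950204 and 2291821 such counts, the floor of 3 counts is 1.54 and 1.31 CPM. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. A gene was detected at 10 or more counts in each library. The comparison of the libraries used a two-sided conditional exact binomial test given TMM-scaled library sizes from edgeR 4.0.16, with Benjamini-Hochberg adjustment over the detected genes and a minimum of 2-fold. Log2 ratios use a prior of 0.5 counts, and their SE covers counting error only. For a few very abundant genes the adjusted p was below what the computation can represent and is not printed. The biological coefficient of variation is the square root of the common dispersion from an intercept-only fit. The quasi-likelihood test was not run because there is no second group. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

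The 25 gene lists, the detection minimum, the tests and the rule for named genes were fixed before the data were examined. The rule names the 20 genes of highest mean CPM, up to 3 of the most abundant detected genes of each list, every gene of the striated muscle list and the 5 largest ratios in each direction among called genes with a mean of at least 10 CPM. For a list's position, 10000 random lists were drawn, each gene from the 40 genes nearest in mean CPM. Lists with under 3 detected genes were given no position. The names Mir486b, Mir497a, Mir124-2hg, Mirlet7j and Mirlet7k were not found in the annotation, and the lists were used without them. A gene annotated as Mir497 was detected but was counted in no list.

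The tests were checked on simulated data, made from the real library sizes except for the list positions. For the comparison of replicate 2 with replicate 1, 280 simulated genes were tested. They carried counting noise only and no spread between animals, so they check the arithmetic of the test and not how often it calls genes between 2 animals. None of the 178 unchanged genes was called, and 18 of 34 genes changed 2-fold, 34 of 34 changed 4-fold and 34 of 34 changed 8-fold were called. The genes changed 2-fold lie at the fold minimum itself, so noise decides on which side of it they fall. A simulated coefficient of variation of 0.3 was estimated as 0.307. For the list positions, log2 ratios were replaced by random values of equal spread, drawn independently for each gene. Of 100 lists with a planted shift of 1 on the log2 scale, 100 fell outside the range, as did 10 of 100 without a shift. The simulated spread was below that of the real log2 ratios, whose SD was 0.752 over 276 genes on unscaled counts. The planted shift also exceeds every list median of the main comparison, so it shows little about smaller shifts. Alternatives changed the scaling, the count minimum, the strand, the denominator, the fold minimum, the dispersion and the libraries used.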

Results

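MicroRNAs were profiled in the gastrocnemius, the large calf muscle of the hind limb, of female mice 2 months old. The animals were B6CASTF1/J, the first-generation cross of C57BL/6J and CAST/EiJ mice. The series has 1 group with 2 libraries of small RNA, labelled biological replicates 1 and 2. The labels number the animals as separate females but give both the same donor code, so the spread between libraries is read as that between animals only as far as the labels go. There is no second condition, and the values describe the muscle and how far the 2 libraries differ. The files list 9410562 reads for replicate 1 and 14377558 for replicate 2. Of these, 1950204 (20.7%) and 2291821 (15.9%) were counted on the own strand of a microRNA gene, so 1 count was worth 0.513 and 0.436 CPM, the usual scaling of counts to library totals. At least 10 counts in each library were reached by 278 of the 2202 microRNA genes, which are called detected here, and 1619 genes had no count in either library.

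The counts, which cover only reads placed in 1 gene, were concentrated in a few microRNAs, led by those of smooth muscle and endothelium. Reads that aligned to several places, 70.1% and 72.3% of those listed, are in no gene. The ranking may thus understate microRNAs with near-identical copies, such as Mir1a and Mir133a, and cannot place them below those named here. The 10 most abundant genes took 68.0% of the counts in replicate 1 and 66.0% in replicate 2, a mean of 67.0% ± 1.42 (SD, n = 2). Mir143, a microRNA of smooth muscle, had the highest mean, 145273 ± 71987 CPM (SD, n = 2), and its spread was the widest of the 20 most abundant genes. It had 196175 CPM in replicate 1 and 94370 CPM in replicate 2, where Mir126a (156853 CPM) and Mir378a (114094 CPM) were above it. Mir126a, which lies in the endothelial gene Egfl7, had 138867 ± 25437 CPM (SD, n = 2). Mir378a, which lies in an intron of Ppargc1b, a coactivator of mitochondrial genes, had 102710 ± 16100 CPM (SD, n = 2). Mir22 had 58873 ± 16282 CPM and Mirlet7g 45449 ± 9429 CPM (SD, n = 2 each). Mir23a, Mir21a, Mir99a, Mirlet7i and Mir206 completed the first 10, at means of 39436, 36173, 34918, 34452 and 34321 CPM. The next 10 were Mir30a, Mir23b, Mir26b, Mir10b, Mirlet7d, Mir30d, Mirlet7b, Mir30e, Mir27b and Mir100, from 31325 CPM down to 8863 CPM. Mirlet7i and Mir27b differed little between the libraries, with SDs of 518 and 96.0 CPM. Mir378a, Mir23a, Mir23b and Mir27b each share a stretch of 20 nt with another microRNA locus, so their counts are uncertain where reads could not be placed.

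**Figure D1:**
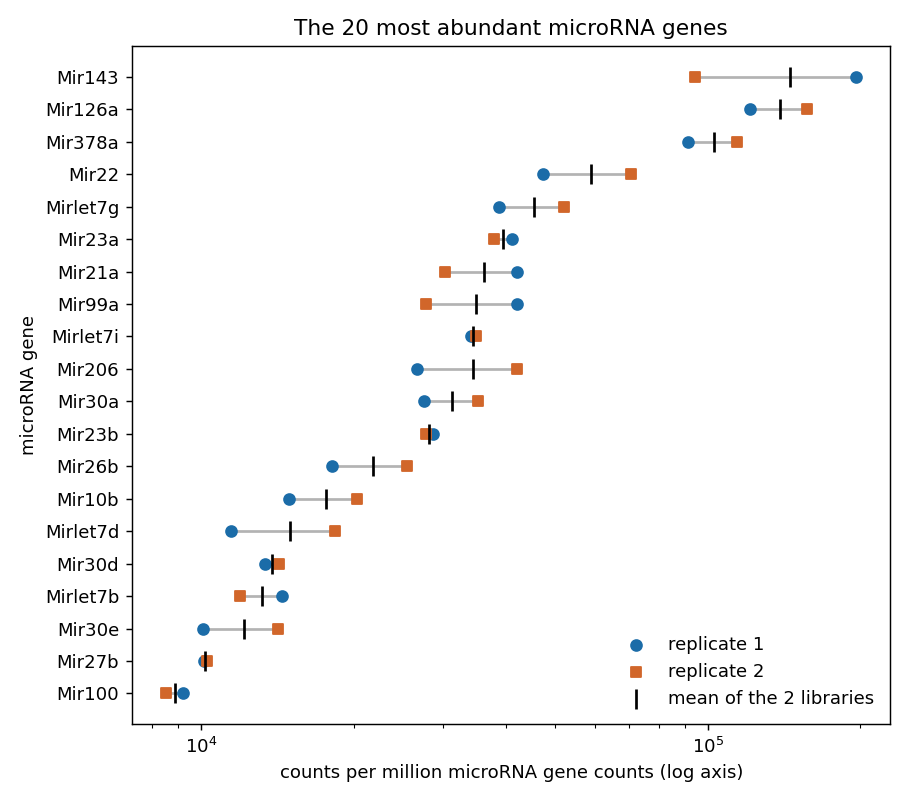
CPM (horizontal log axis) of the 20 most abundant microRNA genes, with circles for replicate 1, squares for replicate 2 and a tick for their mean. Mir143 has the largest gap, from 94370 to 196175, and Mir27b sits near 10184 in both libraries.

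In the mm10 assembly, Mir143 (ENSMUSG00000065445.3) lies on the minus strand of chromosome 18, from 61649196 to 61649258. No annotated gene on that strand, other than microRNA genes, contains it whole. Mir145a (ENSMUSG00000065592.2) lies on the same strand from 61647825 to 61647894. Mir126a (ENSMUSG00000065540.1) is at chromosome 2, 26591357 to 26591429, within an annotated exon of Egfl7. Mir378a (ENSMUSG00000105200.1) is at chromosome 18, 61397835 to 61397900. Mir206 (ENSMUSG00000065559.1) is at chromosome 1, 20679010 to 20679082, in an exon of the long noncoding gene Gm28653, and Mir133b (ENSMUSG00000065480.1) is in the same gene from 20682769 to 20682887. Mir208b (ENSMUSG00000077928.1) lies at chromosome 14, 54975700 to 54975776, in an intron of Myh7, the slow myosin heavy chain. Mir208a (ENSMUSG00000065432.1) lies at chromosome 14, 54949060 to 54949142, in an intron of Myh6. Mir499 (ENSMUSG00000076312.1) lies at chromosome 2, 155622880 to 155622958, in an intron of Myh7b.

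The microRNAs named for striated muscle held 2.79% of counts in replicate 1 (95% exact Clopper-Pearson interval 2.77 to 2.82) and 4.66% in replicate 2 (4.63 to 4.68), a mean of 3.73% ± 1.32 (SD, n = 2). Of the 11 genes in this list, 10 were in the files under their listed names and 9 were detected. Mir206, a skeletal muscle microRNA, carried nearly all of the share, with 52086 and 96104 counts. The other members were low. Mir1a-2 had 212 ± 50.2 CPM, Mir133a-1 48.0 ± 13.5, Mir133b 21.01 ± 3.61, Mir1a-1 13.3 ± 2.15 and Mir133a-2 5.40 ± 0.385 CPM (SD, n = 2 each). All of these 5 genes share a stretch of 20 nt with another locus, and reads that aligned to several places were counted in no gene, so their values leave out any reads that could not be placed. The 6 genes of the Mir1a, Mir133 and Mir206 clusters together held 2.70% and 4.23% of counts. Mir486, in an intron of Ank1, had 777 ± 324 CPM (SD, n = 2). It overlaps Mir3107 on the other strand, and the mark for shared sequence leaves out overlapping genes. Whether reads of Mir486 also align to Mir3107 was thus not checked, and its value may leave out reads that could not be placed. Mir486b was not found by that name in the annotation and is not analysed here.

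The 3 microRNAs carried in myosin heavy chain genes of slow and cardiac muscle stood apart from the rest of the muscle list. Mir499 had 615 counts in replicate 1 and 5722 in replicate 2, and Mir208b had 238 and 1745. Mir499 was higher in replicate 2 by 3.02 on the log2 scale (SE 0.061, counting error) and Mir208b by 2.67 (SE 0.0996), and both were called in the exact binomial test below. Mir208a had 4 and 50 counts, a CPM ratio of 10.6 with an exact binomial 95% interval of 3.91 to 40.6. It missed the minimum in replicate 1 and was therefore not tested, since a minimum in both libraries removes genes that are low in one of them. The list's share of counts was 0.0439% and 0.328%. The other 7 detected muscle genes were all higher in replicate 2 as well, by a median of 0.52 on the log2 scale, and none of them was called. For Mir133b, Mir1a-1 and Mir133a-2 the difference was within counting error (adjusted exact binomial p = 0.334, 0.451 and 0.871).

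Among the lists for other cell types, those of the vessel wall were the largest. The smooth muscle list, Mir143 with Mir145a and Mir145b, took 20.3% of counts in replicate 1 (20.2 to 20.3) and 9.73% in replicate 2 (9.70 to 9.77). The endothelial list, in effect Mir126a, took 12.1% (12.04 to 12.13) and 15.7% (15.64 to 15.73), so the 2 lists differed between libraries in opposite directions. The fibroblast list, with Mir21a, Mir214 and Mir199b as its most abundant genes, took 4.35% and 3.18%. The leukocyte list, led by Mir155, Mir150 and Mir223, took 0.368% and 0.275%. The red cell microRNAs Mir451a and Mir144 took 0.0787% and 0.0460%. Mir338, in an intron of Aatk and known from myelinating glia, made up nearly all of a glial share of 0.308% and 0.0862%. The neural list had 1 detected gene, Mir137, and shares of 0.00938% and 0.00179%. The epithelial list had Mir203 and Mir200c detected and took 0.0338% and 0.0164%. The liver list, with Mir192, Mir122 and Mir194-2, took 0.0193% and 0.0134%. No gene of the pancreas or pluripotent cell lists was detected, and their shares were 0.00097% and 0.00044%, and 0.00041% and 0.00061%, against 0.00015% and 0.00013% for 3 counts. The satellite cell list, with Mir195a and Mir31 detected, took 0.481% and 0.528%. Its member Mir497a was not found by that name, and Mir497, in the cluster of Mir195a with a mean of 786 CPM, was not counted in it. An X-linked group known mainly from testis took 0.00395% and 0.0116%, with Mir547 and Mir201 detected, and the hypoxia microRNA Mir210 took 0.00754% and 0.00467%. All intervals cover counting error only, since amplified reads are not independent molecules.

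**Figure D2:**
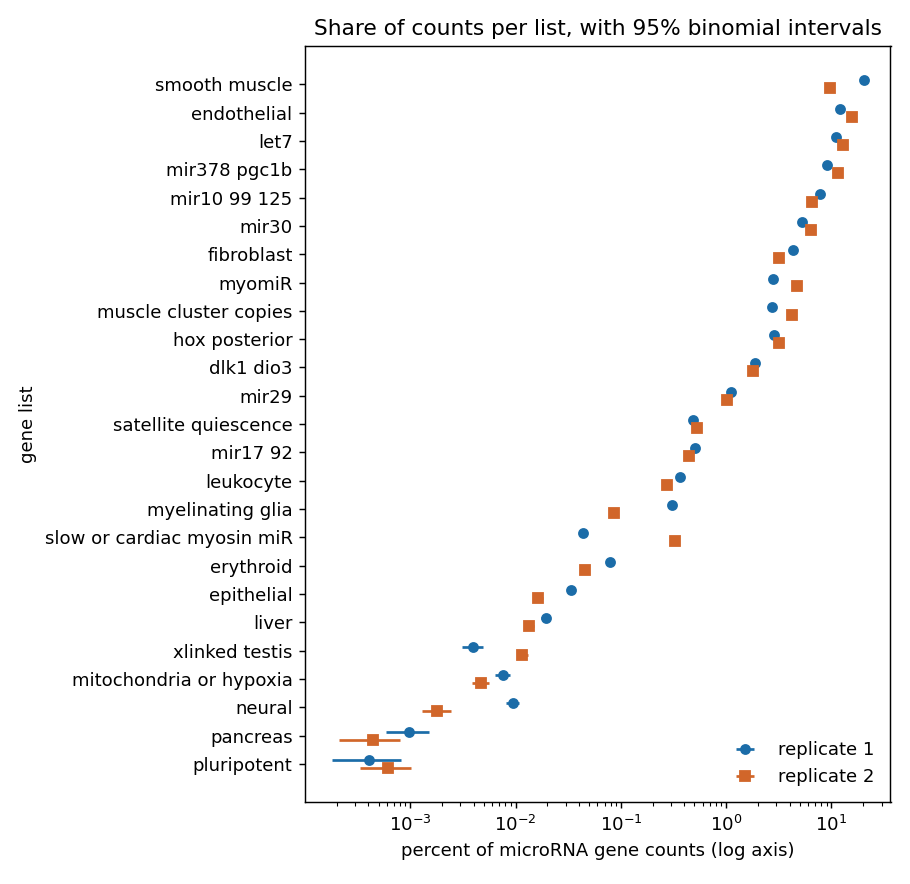
Percent of microRNA gene counts (horizontal log axis) held by each of the 25 gene lists, with circles for replicate 1, squares for replicate 2 and bars for exact 95% binomial intervals. The smooth muscle list is highest in replicate 1 at 20.3% and the slow or cardiac myosin list has the largest ratio between libraries, 0.0439% against 0.328%.

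The lists of microRNA families, genomic regions and Mir378a accounted for much of the remainder. The let-7 family took 10.95% and 12.78% of counts, a mean of 11.9% ± 1.29 (SD, n = 2), mainly as Mirlet7g, Mirlet7i and Mirlet7d. Mir378a alone took 9.13% and 11.4%. The Mir10, Mir99 and Mir125 families took 7.73% and 6.52%, with Mir99a, Mir10b and Mir100 leading. The Mir30 family took 5.20% and 6.45% through Mir30a, Mir30d and Mir30e. MicroRNAs of the Hox clusters took 2.82% and 3.20%. Mir10b lies in an intron of Hoxd3, and Mir10a and Mir196b followed it at 5583 ± 330 and 5317 ± 1096 CPM (SD, n = 2 each). The imprinted Dlk1-Dio3 region took 1.89% and 1.79%, and 45 of its 54 listed genes were detected, led by Mir411, Mir127 and Mir379. The Mir29 family took 1.12% and 1.03%, with Mir29a at 8379 ± 634, Mir29c at 2322 ± 67.5 and Mir29b-1 at 24.9 ± 5.50 CPM (SD, n = 2 each). The Mir17 to Mir92 group took 0.507% and 0.447%, led by Mir93, Mir17 and Mir20a.

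The 2 libraries were then compared gene by gene, which compares these libraries and not conditions. The test called 33 of the 278 detected genes, 7 higher and 26 lower in replicate 2, at least 2-fold and with an adjusted p under 0.05 (two-sided exact binomial test, Benjamini-Hochberg). The 5 with the largest ratios higher in replicate 2 were Mir499, Mir208b, Mir547, Mir190b and Mir201. Mir547 was higher by 1.74 (SE 0.258, adjusted exact p = 3.95e-13), Mir190b by 1.56 (SE 0.241, adjusted exact p = 8.21e-12) and Mir201 by 1.39 (SE 0.272, adjusted exact p = 1.98e-07) on the log2 scale. Mir547 and Mir201 are neighbours on the X chromosome, at 67988374 to 67988451 and 67988096 to 67988161. The 5 with the largest ratios lower in replicate 2 were Mir182, Mir183, Mir122, Mir31 and Mir708. Mir182 and Mir183, a cluster of sensory and epithelial cells on chromosome 6, were 11.7-fold and 11.4-fold lower, from 249 to 24 and from 164 to 16 counts. Mir122, a liver microRNA, was 9.70-fold lower (adjusted exact p = 4.08e-44). Mir31 was 8.86-fold lower (adjusted exact p = 1.33e-19) and Mir708, in an intron of Tenm4, 5.92-fold lower (adjusted exact p = 7.61e-174). Mir137, Mir338, Mir199b and Mir223 were lower by 4.77-fold, 3.51-fold, 3.18-fold and 2.89-fold. Mir145a was 2.11-fold lower and Mir143 2.03-fold lower. By list, the calls were 2 of 9 detected genes for striated muscle, 2 of 2 for smooth muscle, 2 of 5 for leukocytes, 1 of 3 for liver, 3 of 45 for Dlk1-Dio3, 2 of 2 for the X-linked group and 1 of 9 for the Mir17 to Mir92 group. The fibroblast list had 1 of 4, the satellite cell list 1 of 2, and the neural and glial lists 1 of 1 each. The endothelial, red cell, epithelial, let-7, Mir30, Mir29, Mir378a, Mir10, Hox and Mir210 lists had 0 calls, although a test without the fold minimum passes smaller differences. Each list's count was the same when adjusted over the list alone. Mir143 lies close to the 2-fold minimum and was not called with DESeq2 size factors, at −0.99 on the log2 scale. Mir143, Mir145a and Mir201 were not called by the edgeR exact test with an assumed coefficient of variation of 0.2, which called 22 genes. That value is below the 0.352 estimated from these libraries, and with the estimate the same test called 7 genes, namely Mir499, Mir208b, Mir182, Mir183, Mir122, Mir31 and Mir708. The other calls, among them Mir547, Mir190b, Mir201, Mir137, Mir338, Mir199b, Mir223, Mir145a and Mir143, thus hold against counting error and not against the estimated spread. Of these, Mir547, Mir190b, Mir137, Mir338, Mir199b and Mir223 were still called at the assumed 0.2.

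**Figure D3:**
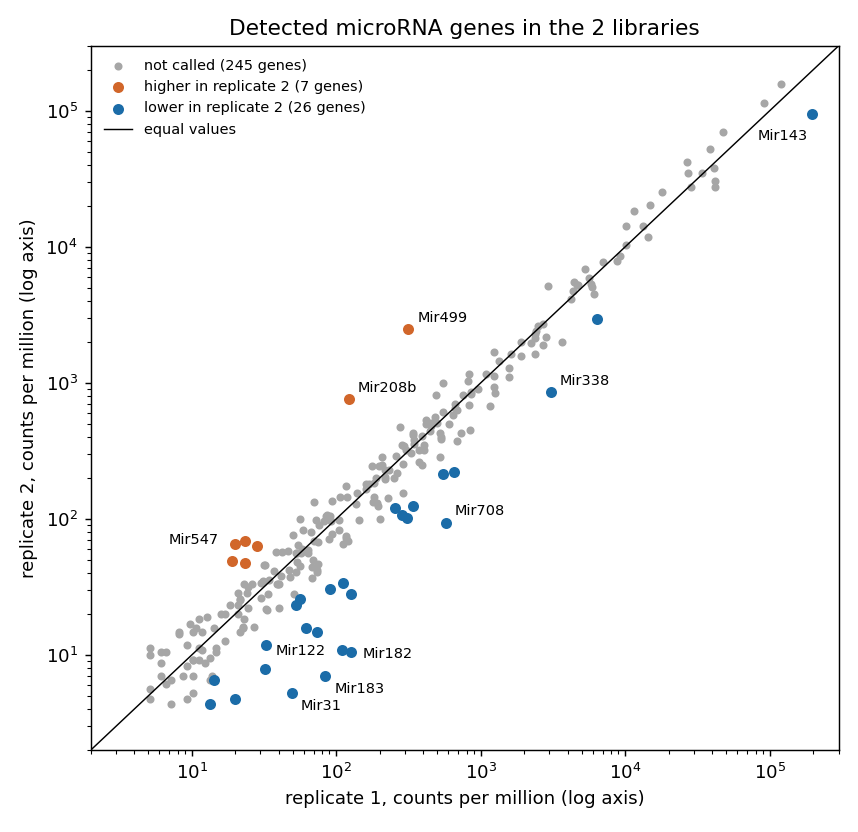
CPM of the 278 detected microRNA genes in replicate 1 (horizontal log axis) and replicate 2 (vertical log axis), with genes called higher and lower in replicate 2 in colour and a line at equal values. Most genes follow the line, while 7 called genes, Mir499 and Mir208b among them, lie above it and 26 called genes lie below it.

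Counting error alone is small at this depth, so the test also passes modest differences. Without a minimum fold, 154 genes had an adjusted p under 0.05. The biological coefficient of variation, estimated by edgeR over the detected genes, was 0.352. Across the detected genes, log2(CPM + 1) of the 2 libraries had a Pearson's r of 0.973 and a Spearman's rho of 0.958, where genes are not independent replicates. A chi-square statistic of 568 per degree of freedom showed that the libraries are not 1 library deposited under both labels.

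Gene lists were placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The muscle list had a median log2 ratio, replicate 2 over replicate 1, of 0.61 (percentile 99.98). Of its 9 detected genes, 9 were higher in replicate 2, although Mir133b, Mir1a-1 and Mir133a-2 only within counting error. The Mir1a, Mir133 and Mir206 clusters, which overlap that list, had 0.45 (percentile 97.76), the Mir30 family 0.44 (percentile 99.33) and the Hox cluster list 0.46 (percentile 98.2). Of the detected genes, 1 of 6 in the Mir30 family and 2 of 5 in the Hox cluster list were lower in replicate 2. The leukocyte list had −0.85 (percentile 0.08), with 3 of 5 detected genes lower, while Mir155 and Mir150 differed by 0.14 and 0.03. The other lists with at least 3 detected genes lay inside the central 95% of random lists. These were the fibroblast list at −0.31, liver at 0.55, let-7 at 0.05, Mir29 at 0.23, the Mir10, Mir99 and Mir125 families at −0.30, Dlk1-Dio3 at −0.10 and the Mir17 to Mir92 group at −0.13. The liver list's median was above 0 although its share was lower in replicate 2, because Mir192 and Mir194-2 were higher and Mir122 was lower. On unstranded counts, the muscle clusters and the leukocyte list lay inside that range, at percentiles 93.26 and 5.19. In simulated data without any shift, 10 of 100 lists fell outside this range where 5% would be nominal, so a position just beyond it is weak. Both the simulated and the random lists drew genes independently, while genes of 1 genomic cluster tended to differ together in these libraries. Percentiles of lists with neighbouring genes may thus be too extreme.

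Most reads in the files were in no microRNA gene. Reads that aligned to several places made up 70.1% and 72.3% of all reads listed, a mean of 71.2% ± 1.60 (SD, n = 2). Unmapped reads made up 7.48% and 9.83%, and uniquely aligned reads outside genes 1.73% and 1.90%. Counts on the strand opposite to a gene summed to 464638 and 684371. All but 33 and 26 of these lay at the 64 genes that overlap a microRNA gene on the other strand, such as Mir126a with Mir126b, where a read on the own strand of one gene is opposite to the other. Reads that were ambiguous without strand equalled 23.8% and 29.9% of the own-strand counts.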

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

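All of the tests in this part were chosen after the results were seen. Reads that aligned to several places, which enter no gene, made up 70.07% of all reads listed in replicate 1 and 72.33% in replicate 2, and are listed because they lie outside the gene counts used. Uniquely aligned reads outside microRNA genes made up 1.73% and 1.90%. Reads opposite to a microRNA gene and in no gene on their own strand numbered 33 and 26, above the limit of 3 counts.

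Some microRNA genes with near-identical copies held few counts beside single-copy neighbours of their cluster. Of all genes, 69 of 1087 with copies were detected against 209 of 1115 others, while the medians among detected genes, 160 and 98.7 CPM, leave out the genes that missed detection. In the cluster of Mir133b and Mir206, the log2 difference of Mir133b from Mir206 was −10.6, and that of Mirlet7c-1 from Mir99a was −7.76. If reads of such genes were set aside as aligning to several places, a candidate explanation, copies would be lower in most clusters. They were lower in 12 of 16 clusters, which misses the threshold in an exact two-sided sign test (p = 0.07681), and in the Dlk1-Dio3 cluster of Mir379 the copies were higher by 3.11. Reads that aligned to several places are in no gene by the way reads were counted, but the sign test cannot decide how many came from these genes. It took detected genes only, which leaves out copies that missed detection. The mark for copies also needs only 1 shared stretch of 20 nt, so it covers genes such as Mir411, with 11431 and 11666 counts. Low transcription of the loci is the alternative, and a median difference of −4.998 log2 units within clusters speaks against it. That value does not decide, because the clusters go both ways, so the contributions of the 2 explanations cannot be told apart here.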

How the results depend on the processing

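Apart from the calls between libraries, most values kept their direction and their side of the threshold, and the ratio of no named called gene changed sign under an alternative that gave a value. Of the list medians, that of Dlk1-Dio3, inside the random range throughout, went from −0.10 to 0.07 at a minimum of 100 counts, and no other changed sign. The alternatives without genes that share 20 nt, with a minimum of 1 or 100 counts or the estimated coefficient of variation for differing genes and with a minimum of 1 count for list medians were chosen after seeing the data. Detected genes numbered 425 at a minimum of 1 count and 174 at 100, which follows from the minimum itself, and 291 to 296 when either library was left out. The 33 differing genes became 154 without a minimum fold and 12 at a minimum of 100 counts, all 12 among the 33, and 7 with the edgeR exact test at the estimated coefficient of variation of 0.352, all among the 33. That estimate comes from the same 2 libraries and includes their differences. Other settings gave 22 to 45 genes, the most at a minimum of 1 count. The correlation was 0.988 with no filter on low counts, where most genes are at 0 in both libraries. The coefficient of variation ranged from 0.287 to 0.381. Summing copies left the share of the 10 most abundant genes as it was, since none of them has a numbered copy.

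Shares depended on the denominator. As percent of all reads listed, the means were 0.661 for the muscle list, 0.616 for its clusters, 0.0919 for satellite cells, 2.503 for endothelium, 2.87 for smooth muscle, 0.705 for fibroblasts, 0.0118 for red cells, 0.060 for leukocytes, 0.0388 for glia, 0.0048 for epithelium, 0.0031 for liver, and 0.0001 for pancreas and for pluripotent cells. They were 2.15 for let-7, 1.05 for the Mir30 family, 0.198 for Mir29, 1.86 for Mir378a, 1.32 for the Mir10, Mir99 and Mir125 families, 0.547 for Hox, 0.339 for Dlk1-Dio3, 0.0882 for the Mir17 to Mir92 group, 0.0013 for the X-linked group and 0.0012 for Mir210. On unstranded counts, reads at genes that overlap on both strands are ambiguous by construction, so endothelium fell to 0.0001%, and glia and Mir378a to 0%. Red cells were then at 0.0128%, the muscle clusters at 4.75%, satellite cells at 0.692%, fibroblasts at 5.13%, liver at 0.0224%, pluripotent cells at 0.0007%, let-7 at 16.0%, Mir29 at 1.47%, the Mir10, Mir99 and Mir125 families at 9.72%, Hox at 4.13%, Dlk1-Dio3 at 2.34%, the Mir17 to Mir92 group at 0.652% and Mir210 at 0.0083%. Without Mir143, the most abundant gene, smooth muscle held 0.562%, satellite cells 0.591%, let-7 13.9%, the Mir30 family 6.79%, Mir29 1.26%, Mir378a 11.98%, the Mir10, Mir99 and Mir125 families 8.41%, Hox 3.52%, Dlk1-Dio3 2.16% and the Mir17 to Mir92 group 0.562%. Without genes that share 20 nt, Mir378a drops out (0%), and the values were 0.641% for satellite cells, 17.7% for endothelium, 4.76% for fibroblasts, 0.0003% for pluripotent cells, 14.3% for let-7, 7.36% for Mir30, 8.99% for Mir10, Mir99 and Mir125, 3.64% for Hox, 1.46% for Dlk1-Dio3 and 0.555% for Mir17 to Mir92.

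On unstranded counts, the list median was 0.397 (percentile 93.26) for the muscle clusters and −0.39 (percentile 5.19) for leukocytes, both back inside the range, while the Mir10, Mir99 and Mir125 families moved outside it at −0.28 (percentile 2.21). The first 2 lost Mir1a-2 and Mir142, whose reads are ambiguous without strand, which left 5 and 4 genes. For the third, with 8 genes in both, the cause was not tested. Among single named genes, 46 mean CPM values moved by more than the spread on unstranded counts. The ratios of Mir143, Mir145a and Mir201 missed the threshold in the edgeR exact test with an assumed coefficient of variation, and that of Mir143 also with DESeq2 size factors. With the estimated one, 9 of the 16 named ratios missed it. Leaving out a library gives the share in the other, which the report prints. Correlation, coefficient of variation, differing genes and list medians cannot be had from 1 library. No paired analysis was possible because the series has 1 group. Depth limits genes near 10 counts, such as Mir133a-2 with an SE of 0.594 on the log2 scale.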

Other observations

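Some genes called lower in replicate 2 against counting error, and not with the estimated coefficient of variation, belong to none of the fixed lists and were picked after their values were seen. Mir138-1 on chromosome 9 and Mir138-2 on chromosome 8, which share sequence, were 4.40-fold and 3.82-fold lower. Mir204, in an intron of Trpm3, was 2.57-fold lower, from 554 to 247 counts. Mir574, in an intron of Fam114a1, was 2.64-fold lower and Mir34c 2.87-fold lower. Mir669c and Mir669o, both in an intron of Sfmbt2, were 2.69-fold and 2.11-fold lower, and they share a stretch with 45 and 56 other loci, so their counts are uncertain. Higher in replicate 2, outside the largest 5, were Mir6236 by 1.20 and Mir543 by 1.04 on the log2 scale.

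All tests of explanations in this part were chosen after the results were seen. Mir208a, Mir208b and Mir499 were higher together in replicate 2, and as a list they had a median of 3.03 (percentile 100) when genes with at least 1 count per library were kept. The tables argue against library scaling, since a factor acts on every gene alike, and on unscaled counts the 276 other detected genes had a median log2 ratio of 0.164 (SD 0.752) against at least 2.87 for the 3. More muscle fibre of every kind would raise the other muscle genes alike, but their median was 0.522 with an SD of 0.245. A larger share of slow fibres, through the animal or the part of the muscle taken, may account for it and stays open. Mir206, known to be higher in slow muscle, had a log2 ratio of 0.685, ranking 2 of 7, which decides nothing.

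The shares of the smooth muscle, glial, neural, epithelial, liver and leukocyte lists were higher in replicate 1, and Mir143, Mir338, Mir137, Mir122 and Mir223 were called against counting error, of which only Mir122 with the estimated coefficient of variation, while 2 of the 3 detected liver genes were higher in replicate 2. Less muscle with more of every other cell type alike would also raise Mir126a in replicate 1, but its log2 ratio was 0.41, in favour of replicate 2, and at least 0.376 under each scaling. More tissue around the muscle, such as nerve or large vessels, could still contribute. Of the 14 detected genes of these 6 lists, 5 of them from the leukocyte list, 10 were lower in replicate 2 against 132 of 264 other genes (one-sided Fisher's exact p = 0.0978), which misses the threshold but depends on the lists taken. The 6 were picked after their shares were seen, and the p was 0.0219 with the fibroblast and red cell lists added (15 of 20 against 127 of 258) and 0.042 with all 10 lists for other cell types, endothelium included (15 of 21 against 127 of 257), so the explanation stays open. Fisher's exact test takes genes as independent, while these lists hold neighbours of 1 cluster, such as Mir143 with Mir145a, so each p may be too small. The genes of the lists are also expressed outside the cells they are named for, and no biological difference between the animals was tested.

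MicroRNAs of 1 genomic cluster tended to differ between the libraries together, but not all did. In the cluster of Mir379, Mir543 and Mir496a were called in opposite directions, at log2 ratios of 1.04 and −1.12. Over 40 clusters with 136 detected genes, the SD of log2 ratios within clusters was 0.391, against a median of 0.789 in random groups of detected genes (permutation p = 0.0001, the smallest that 10000 permutations give). Random groups were not matched on expression, and the Dlk1-Dio3 list, with 45 detected genes, supplies many of the 136. Independent scatter of each gene between libraries is thus unlikely to produce such ratios, and shared transcription of a cluster is a candidate explanation that was not tested further.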
